A study of Rattus norvegicus with 31 samples.

How the data were processed

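RNA was measured in rat (Rattus norvegicus) kidney cortex and colon in 3 groups: normal control (NC), high-salt model (HS), and high salt with calcitriol, the active form of vitamin D (CAL). The cortex had 5 NC, 4 HS and 6 CAL libraries, and the colon 5 NC, 5 HS and 6 CAL libraries, 31 in all. Replicates are separate samples per the labels, so each p measures variation between samples. Diet, dose, duration, strain, sex and hour of collection were not used here. RNA was extracted with TRIzol, and libraries were made with a tagmentation kit that does not mark the strand, then sequenced on a NextSeq 500. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trimmomatic 0.39, aligned to Rnor_6.0 with HISAT2 2.1.0 and counted with featureCounts 1.6.5. The gene annotation and strand setting were not stated.

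The deposited values are counts: whole-number reads per gene, not normalised, for 20207 gene symbols. Of these genes, 2839 had no count in any library, and the 13 protein-coding genes of the mitochondrial genome were listed at 0 throughout. Total counts ran from 289529 to 2265164 per cortex library and from 267976 to 918820 per colon library, with 10618 to 13776 genes counted per library. A count of 0 allows between 1.32 and 11.2 counts per 1e6 counts (CPM) across the libraries, taking 3 counts as the limit. That limit, and the exact (Clopper-Pearson) 95% intervals given for shares of single libraries, cover counting error only.

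Genes were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, fitted per tissue to the 3 groups, after trimmed-mean (TMM) scaling and the edgeR filter on low counts (minimum count 10, minimum total 15). Adjusted p are Benjamini-Hochberg values over the genes tested in a comparison, and the threshold was 0.05. The comparisons were HS with NC, CAL with HS and CAL with NC. Standard errors (SE) of fold changes were taken from the quasi-likelihood F. The difference between tissues (the colon effect minus the cortex effect) was fitted over genes that passed the filter in both tissues. Levels of genes are TMM-scaled CPM over the tested genes, as mean ± SD. The level of gut segment markers is plain CPM, and the haemoglobin share is a percent of all counts, compared by exact two-sided permutation of the libraries, with Benjamini-Hochberg adjustment over 6 comparisons. The test was also fitted on simulated counts with the same groups and totals. Of genes changed by 1 on the log2 scale between HS and NC, it recovered 59.7% in the cortex and 27.3% in the colon. Of those changed by 2, it recovered 96.8% and 90.6%. The simulated variation came from all libraries of each tissue, colon HS replicate 3 included.

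Lists of genes (28 by function, 32 of cell type markers) were compared with all other tested genes by limma 3.58.1 camera on voom values, with a preset correlation between genes of 0.01 and, beside it, with the correlation estimated per list. Lists with at least 5 tested genes were used. Of 1086 list entries, 1038 were matched to listed symbols, 5 of them through synonyms. Principal components used the 500 most variable genes.

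These groups, tests, lists and the rule for naming genes were fixed before the data were examined. Under that rule, HS against NC and CAL against HS give in each tissue the 10 genes higher and the 10 lower with the largest fold change among those past the threshold with a mean log2 CPM of at least 1 and an assigned symbol. Where none passes in a direction, the 5 with the smallest p are given as not past the threshold. CAL against NC and the difference between tissues give 5 each way. Each described list gives up to 4 members with the smallest p, and Cyp24a1, Vdr, Agt, Scnn1a and Slc12a3 are always included. Some genes that the rule names are not reported here. A gene named outside the rule is said to be so.

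Alternatives fixed beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a filter on 1 CPM in at least 4 libraries, a fit to the compared groups alone, robust empirical Bayes, voom with library weights, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were thinning all libraries to the shallowest, leaving out erythrocyte genes, the haemoglobin share as a covariate, colon fits without HS replicates 3 and 4, and colon fits without HS replicate 3 with marker covariates. No library was left out of the results given first. No pair of libraries of a group held identical values. Gene length and GC content were not used here.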

Results

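In the kidney cortex, the high-salt libraries separated from the controls on the first principal component, which held 21.4% of the variance. NC libraries lay between -9.68 and -4.47 and HS libraries above the highest of them, up to 16.3, with the CAL libraries from -9.52 to 5.48. In the colon the first component held 41.5% of the variance, and HS replicate 3 lay at -52.9 and HS replicate 4 at -20.3, with the other colon libraries between -11.0 and 14.2.

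Erythrocyte transcripts were the most changed genes of the cortex under high salt. The haemoglobin chain genes Hba-a1 and Hba-a2 fell from 4123 ± 2790 and 1843 ± 1209 CPM in NC (n = 5) to 444 ± 130 and 204 ± 71.9 CPM in HS (n = 4). The log2 fold changes were -3.22 (SE 0.36) and -3.22 (SE 0.35), each with an edgeR quasi-likelihood adjusted p of 9.44e-06. Hbb fell by 2.67 (SE 0.36, adjusted p = 1.43e-04), Hba-a3 fell by 2.41 (SE 0.54, adjusted p = 0.00776, lost with voom and library weights at 0.173), and Alas2, the erythroid enzyme of haem synthesis, fell by 3.46 (SE 0.57, adjusted p = 0.00105). Every HS library lay below every NC library for Hba-a1, Hba-a2, Hbb and Alas2. The erythrocyte list (7 genes tested, 6 lower over all genes and 6 adjusted over the list alone) passed limma camera with an adjusted p of 5.05e-07, with every library left out in turn, but adjusted p = 0.134 with an estimated correlation. Hbb-bs (-4.30, adjusted p = 0.0188 by edgeR quasi-likelihood) was lost without NC replicate 2 (0.0726) and HS replicates 1 (0.0541), 2 (0.0633) or 4 (0.05004) and with robust empirical Bayes (0.0933), and the platelet gene Pf4 (-1.84, adjusted p = 0.0196) without HS replicate 4 (0.0734). When the haemoglobin share entered the edgeR fit as a covariate, 2 cortex genes passed between HS and NC in place of 831 and neither was among those 831. That share is built from the haemoglobin genes themselves, and 77.9% of its variance lay between the groups. Adding it takes out much of the group difference of any gene. A call that it ends, here or below, is therefore not tested by it.

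The haemoglobin genes together held 0.980 ± 0.650% of cortex counts in NC, 0.127 ± 0.0353% in HS and 0.459 ± 0.114% in CAL (n = 5, 4 and 6). HS lay below NC by a log2 difference of -2.73 and CAL above HS by 1.86, each with an adjusted p of 0.0159 by exact permutation, while CAL and NC differed by -0.87 (adjusted p = 0.0857, exact permutation). The colon shares were 0.132 ± 0.0971%, 0.0235 ± 0.0116% and 0.105 ± 0.0717% (n = 5, 5 and 6). The log2 differences were -2.33 for HS against NC (adjusted p = 0.0159, exact permutation), 1.97 for CAL against HS (adjusted p = 0.0422) and -0.36 for CAL against NC (adjusted p = 0.630).

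**Figure D1:**
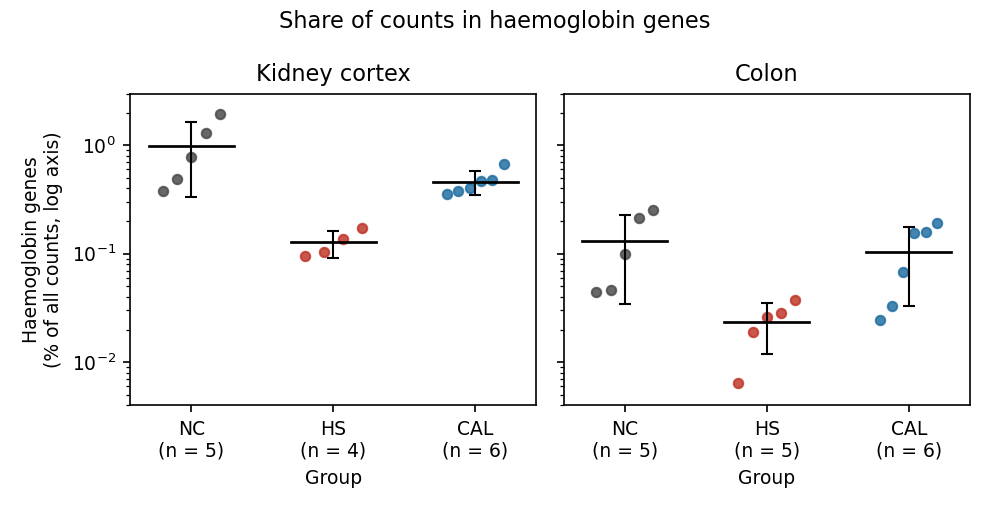
Percent of all counts in haemoglobin genes (log axis) per library in kidney cortex and colon for NC, HS and CAL, with points for libraries and lines for group means. The cortex means are 0.980%, 0.127% and 0.459%, and the colon means 0.132%, 0.0235% and 0.105%.

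Among calcium-handling genes, Trpv5 and Calb1 rose in the high-salt cortex. Trpv5, the apical calcium channel of the distal tubule, rose from 3.68 ± 2.17 CPM in NC to 18.7 ± 9.15 CPM in HS (log2 fold change 2.33, SE 0.46). Calb1, its cytosolic calcium-binding partner, rose from 558 ± 82.7 to 1394 ± 343 CPM (1.32, SE 0.28). The edgeR quasi-likelihood adjusted p were 0.00361 and 0.00534, with no overlap between the groups for either gene. Among transporters, the urate transporter Slc22a12 fell from 835 ± 92.8 to 446 ± 46.5 CPM (-0.91, SE 0.12, adjusted p = 1.43e-04). The ammonia transporter Rhbg fell by 0.97 (adjusted p = 0.00449) and the intercalated-cell water channel Aqp6 fell by 1.51 (adjusted p = 0.00939), while the neutral amino acid transporter Slc6a19 rose by 0.77 (adjusted p = 0.00743). The metabolic genes Khk (-0.66), Acads (-0.73) and Eno1 (-0.56) fell (adjusted p = 0.00449, 0.00449 and 0.00517), as did Mlph (-1.93, adjusted p = 0.00119). Wee1, a kinase that holds back entry into mitosis, rose from 12.3 ± 3.69 to 43.6 ± 3.75 CPM (1.79, SE 0.27, adjusted p = 4.48e-04). Dnajb9, a chaperone of the endoplasmic reticulum, rose by 1.29 (adjusted p = 7.66e-04), Nr1d2 by 0.94 (adjusted p = 0.00923), Ebag9 by 1.44, Cert1 by 1.44, Smc4 by 1.43 and Ankrd37 by 1.39 (adjusted p = 0.00392, 0.0115, 0.0122 and 0.0111). The Trpv5 level in NC lay near the limit of counting, since a count of 0 allows 2.42 to 5.84 CPM in those libraries. Trpv5 passed the low-count filter in 8 of the 15 fits with 1 library left out and passed edgeR in each of those 8. The other genes of this paragraph passed edgeR with every cortex library left out in turn, and none, Trpv5 included, passed with the haemoglobin share as a covariate.

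In all, 831 of 7524 cortex genes passed between HS and NC by edgeR quasi-likelihood, 553 higher and 278 lower, and 175 of them changed by more than 1 on the log2 scale. At an unadjusted p under 0.05 there were 2055 genes, where chance gives 376.2. Over all tested genes the groups did not overlap for 13.1%, where chance gives 1.59%. DESeq2 gave 798 genes and voom with library weights 1032. The count fell to 553 without NC replicate 3, 393 without HS replicate 1, 324 without HS replicate 2 and 469 without HS replicate 4.

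Several cortex changes under high salt were lost when 1 HS library was left out. Renin-angiotensin and inflammatory transcripts among these were Atp6ap2, the prorenin receptor (0.63, edgeR quasi-likelihood adjusted p = 0.0118, and 0.0512 without HS replicate 1), Il33 (0.55, 0.0171, and 0.0631 without HS replicate 2) and Cxcl12 (0.71, 0.0158, and 0.1001 without HS replicate 2). B2m (0.55, adjusted p = 0.0127) and Cycs (0.81, adjusted p = 0.0171) were lost without HS replicate 1 (0.0567 and 0.0989), and Col4a2 (-1.62, adjusted p = 0.0123) and Ptges2 (-0.58, adjusted p = 0.0200) without HS replicate 4 (0.0628 and 0.0745). Nfe2l2 (0.73, adjusted p = 0.0135) was lost without HS replicates 2 (0.0590) or 4 (0.0554), and Tsc22d3 (0.95, adjusted p = 0.0196) without HS replicates 2 (0.0711) or 4 (0.0889). The same holds for Cdc25b (-2.58, adjusted p = 0.0144) without HS replicates 2 (0.0621) or 4 (0.05004) or with voom and library weights (0.230), and for Lin54 (1.51, adjusted p = 0.0164) without HS replicates 1 (0.0647) or 2 (0.0558). Aadac (1.70, adjusted p = 0.0223) was lost without HS replicates 1 (0.101) or 4 (0.0590). Robust empirical Bayes also ended the calls of Cycs (0.0598) and Tsc22d3 (0.0758). Thinning ended those of Atp6ap2 (0.0509), Cxcl12 (0.147) and Ptges2 (0.0764), and the haemoglobin covariate ended all calls of this paragraph.

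Other cortex genes past the threshold between HS and NC that the rule names were each lost when single libraries were left out. Given for each are the log2 fold change, the edgeR quasi-likelihood adjusted p, the number of libraries whose removal ended the call and the highest adjusted p reached. Among the largest changes were Rbp4 (1.49, 0.0367, lost in 7, up to 0.0903) and Aida (1.40, 0.0322, lost in 5, up to 0.112). Klk1c6 was also among them. Aida was tested in 14 and Klk1c6 in 11 of the 15 fits, and the other genes in all 15. Values for Klk1c6 and the vitamin D-binding protein were Klk1c6 (-2.23, 0.0276, lost in 3, up to 0.0833) and Gc (-1.28, 0.0367, lost in 6, up to 0.162). Genes of sterol synthesis were Dhcr7 (-0.995, 0.0295, lost in 4, up to 0.125) and Sc5d (0.54, 0.0486, lost in 10, up to 0.205). Oxidase and oxidative stress genes were Nox4 (0.65, 0.0300, lost in 6, up to 0.153), Rac2 (-0.997, 0.0367, lost in 5, up to 0.125), Cat (0.41, 0.0281, lost in 4, up to 0.106) and Gsta2 (-1.25, 0.0350, lost in 5, up to 0.150). Those of the respiratory chain were Ndufb5 (0.48, 0.0263, lost in 5, up to 0.105) and Ndufv1 (-0.39, 0.0277, lost in 3, up to 0.116). Metabolic and stress genes were Slc2a5 (-1.04, 0.0310, lost in 5, up to 0.146), Pkm (-0.67, 0.0456, lost in 9, up to 0.112), Nr3c1 (0.78, 0.0390, lost in 8, up to 0.140) and Hspd1 (0.35, 0.0375, lost in 9, up to 0.109). Immune genes were RT1-A1 (-0.79, 0.0356, lost in 6, up to 0.121) and RT1-Db1 (-1.12, 0.0324, lost in 5, up to 0.138). Others were RT1-Ba (-1.12, 0.0492, lost in 10, up to 0.196) and Ccl5 (-1.29, 0.0437, lost in 7, up to 0.143). Markers of tubule and endothelium were Tmem52b (0.53, 0.0384, lost in 6, up to 0.105), Krt8 (-0.44, 0.0453, lost in 9, up to 0.188) and Tie1 (-0.89, 0.0249, lost in 5, up to 0.0760). Fibroblast genes were Dpt (0.80, 0.0364, lost in 6, up to 0.144) and Gsn (-0.54, 0.0367, lost in 6, up to 0.113). A gene of the surface colonocyte list also passed in the cortex, Guca2a (-1.12, 0.0479, lost in 10, up to 0.176). The haemoglobin covariate ended every call of this paragraph. It alone among the 8 to 11 alternatives beyond single libraries ended those of Dhcr7, Ndufb5 and RT1-A1, while 7 ended that of Sc5d, 6 that of RT1-Ba and 5 that of Guca2a.

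Some clock genes differed in the high-salt cortex: the core activator Arntl was at -1.43 (SE 0.46), and Dbp at 0.96 (SE 0.30), Usp2 at 0.84 (SE 0.25) and Nr1d2 at 0.94 (SE 0.22), with edgeR quasi-likelihood adjusted p of 0.0474, 0.0363, 0.0334 and 0.00923. Of these, Nr1d2 passed with every library left out, and the haemoglobin covariate ended all 4 calls. Arntl was lost without NC replicates 1 (0.0557), 2 (0.109), 3 (0.0573) or 5 (0.0954) and without HS replicates 1 (0.0516), 2 (0.168), 3 (0.0886) or 4 (0.103). Dbp was lost without NC replicates 2 (0.0815) or 5 (0.0793) and HS replicates 1 (0.103), 2 (0.0587), 3 (0.0836) or 4 (0.0502), and Usp2 without NC replicates 1 (0.0723), 3 (0.0600) or 5 (0.0706) and HS replicates 1 (0.101), 3 (0.0546) or 4 (0.0898). Other alternatives ended the calls of Arntl (1 CPM filter 0.0552, voom with library weights 0.0661, replicate block 0.0659), Dbp (DESeq2 0.0954, robust empirical Bayes 0.125) and Usp2 (thinning 0.0699). The clock list (12 genes, 3 higher and 1 lower over all genes, 4 and 2 adjusted over the list alone) did not pass limma camera (adjusted p = 0.435).

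The glucose metabolism and antigen presentation lists had negative medians between HS and NC cortex and did not pass. The glucose metabolism list (18 genes, 4 lower over all genes and 5 lower adjusted over the list alone, median -0.18) and the antigen presentation list (14 genes, 1 higher and 3 lower over all genes, 1 and 6 adjusted over the list alone, median -0.35) both had a limma camera adjusted p of 0.0792. The vitamin D target and calcium transport list (15 genes, 2 higher over all genes, and 2 higher and 1 lower adjusted over the list alone) had an adjusted p of 0.407, and the renin-angiotensin-aldosterone list (11 genes, 2 higher both ways) one of 0.477. Of the genes always reported, Agt, Cyp24a1, Vdr, Scnn1a and Slc12a3 did not pass by edgeR quasi-likelihood between HS and NC. Agt was at -0.46 (adjusted p = 0.183), Cyp24a1 at -0.29 (0.595), Vdr at -0.09 (0.851), Scnn1a at -0.15 (0.786) and Slc12a3 at -0.02 (0.978).

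Cyp24a1 was higher in the cortex with calcitriol than with high salt alone. Cyp24a1, the vitamin D 24-hydroxylase and a target of the vitamin D receptor, was at 69.6 ± 15.5 CPM in NC, 58.8 ± 21.4 CPM in HS and 151 ± 72.1 CPM in CAL (n = 5, 4 and 6). The rise from HS to CAL was 1.46 (SE 0.30) with an edgeR quasi-likelihood adjusted p of 0.0221 and 6 of 6 CAL libraries above the HS mean. That call was lost without HS replicates 1 (0.0900), 2 (0.0697) or 4 (0.0868), with robust empirical Bayes (0.0879) or the replicate block (0.0811), and when thinned (0.0741). Synpo, a podocyte actin-binding protein, rose from 26.4 ± 4.51 to 68.9 ± 10.4 CPM (1.33, SE 0.20). The actin-binding gene Cotl1 rose from 131 ± 32.2 to 283 ± 55.1 CPM (1.14, SE 0.17). Each had an edgeR adjusted p of 0.00252, no overlap between the groups and a pass with every library left out in turn. The podocyte genes Nphs1 (-0.26) and Wt1 (0.39) did not pass (adjusted p = 0.663 and 0.542). With the haemoglobin share as a covariate Cyp24a1, Synpo and Cotl1 had edgeR adjusted p of 0.207, 0.144 and 0.152.

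**Figure D2:**
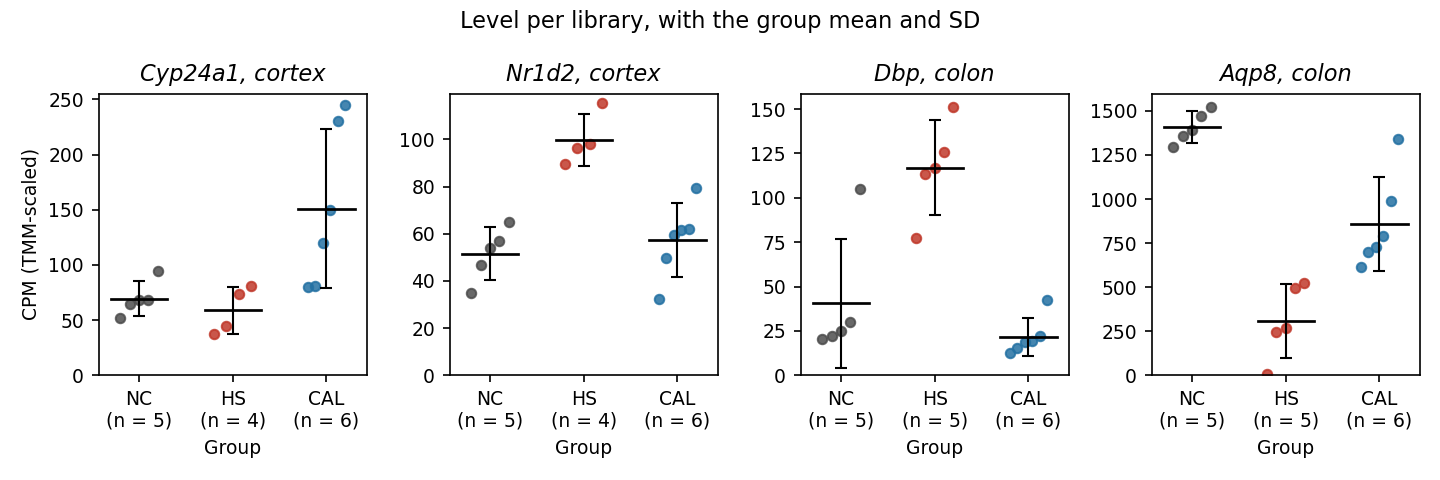
TMM-scaled CPM of 4 genes per library in NC, HS and CAL, with points for libraries and bars for the group mean and SD. Cortex Cyp24a1 has means of 69.6, 58.8 and 151 CPM, and colon Aqp8 means of 1407, 308 and 859 CPM.

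Erythrocyte genes were higher again in CAL than in HS cortex: Hba-a1 and Hba-a2 by 1.92 and 1.91 (edgeR quasi-likelihood adjusted p = 0.0105 for both, lost without HS replicate 2 at 0.0697), and Hbb by 1.76 (adjusted p = 0.0150, lost without HS replicates 2 at 0.0817 or 4 at 0.0776). With robust empirical Bayes these 3 calls were lost too (0.0800, 0.0794 and 0.0996). The erythrocyte list (4 of 7 genes higher over all genes, 6 higher adjusted over the list alone) had a limma camera adjusted p of 1.18e-06 and passed with every library left out, with adjusted p = 0.164 with an estimated correlation. Genes lower in CAL than in HS included Arl6ip6 (-1.27, edgeR adjusted p = 0.0141, lost without HS replicate 2 at 0.0697), Cd200 (-1.11, adjusted p = 0.0221, lost without HS replicate 2 at 0.149). Others were Nucb2 (-1.30, adjusted p = 0.0146, lost without HS replicates 1 at 0.0817 or 2 at 0.0697) and the histamine-degrading enzyme Hnmt (-0.87, adjusted p = 0.0221, lost without HS replicates 1 at 0.0931 or 2 at 0.0819). Wee1 fell by 1.21 (adjusted p = 0.0199, lost without HS replicates 1 at 0.0686, 2 at 0.0817 or 4 at 0.0591), and Slc22a12 rose by 0.56 (adjusted p = 0.0273, lost without HS replicates 1 at 0.0931, 2 at 0.0817 or 4 at 0.0853). Mlph rose by 1.61 (adjusted p = 0.0221, lost without HS replicates 1 at 0.0856, 2 at 0.0817 or 4 at 0.0837, or CAL replicate 1 at 0.0526). Pdcd10 fell by 0.87 (adjusted p = 0.0273, lost without HS replicates 1 at 0.145, 2 at 0.0678 or 4 at 0.0853, or CAL replicate 1 at 0.0661). The replicate block also ended the calls of Cd200 (0.0774), Nucb2 (0.0662), Wee1 (0.0735), Slc22a12 (0.0829) and Pdcd10 (0.101). Thinning ended those of Mlph (0.0805), Cd200 (0.165), Wee1 (0.234) and Pdcd10 (0.156), and the haemoglobin covariate ended every gene call of this paragraph.

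In all, 57 of 7524 cortex genes passed between CAL and HS by edgeR quasi-likelihood, 20 higher and 37 lower, with 1219 at an unadjusted p under 0.05. Over all tested genes the groups did not overlap for 4.17%, where chance gives 0.952%. DESeq2 gave 105 genes and voom with library weights 62, and without the erythrocyte genes edgeR gave 15 higher and 18 lower. The count was 10, 2, 28 and 15 without HS replicates 1, 2, 3 and 4, and 28, 35, 27 and 33 without CAL replicates 1, 3, 4 and 6. Between CAL and HS, Vdr (0.50, adjusted p = 0.287), Agt (0.37, 0.409), Scnn1a (0.09, 0.921) and Slc12a3 (0.25, 0.609) did not pass.

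Other cortex genes past the threshold between CAL and HS that the rule names were also lost when single libraries were left out, given in the same way (edgeR quasi-likelihood adjusted p). Those higher were Myo19 (1.37, 0.0376, lost in 7, up to 0.163) and Rbm38 (1.26, 0.0410, lost in 7, up to 0.163). Those lower were Tsx (-1.22, 0.0376, lost in 7, up to 0.163), Marcks (-1.22, 0.0376, lost in 8, up to 0.120) and Arhgap5 (-1.02, 0.0410, lost in 8, up to 0.127). Lower too were Lrrc19 (-0.96, 0.0410, lost in 8, up to 0.210) and Sc5d (-0.75, 0.0405, lost in 8, up to 0.187). Also past the threshold were Alas2 (2.48, 0.0475, lost in 11, up to 0.134), Slc6a19 (-0.68, 0.0446, lost in 11, up to 0.188) and Nr1d2 (-0.85, 0.0476, lost in 12, up to 0.174). The haemoglobin covariate ended every call of this paragraph, and of the 9 to 11 alternatives beyond single libraries from 2 (Myo19, Marcks) to 7 (Nr1d2) ended a call.

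Macrophage genes (Aif1 -0.68, C1qb -0.61, C1qa -0.49, Lyz2 -0.31) and thick ascending limb genes (Tmem207 -0.96, Slc12a1 -0.55, Cldn16 -0.49, Umod -0.25) were lower as lists in CAL than in HS cortex (medians -0.33 and -0.25, limma camera adjusted p = 0.0406 for both, 0.630 for both with an estimated correlation). Over all genes no member of either list passed, and 1 of each was lower adjusted over the list alone. The macrophage list was lost without HS replicate 3 (0.0819) and CAL replicates 1 (0.226) or 3 (0.0561), and the thick ascending limb list without HS replicates 3 (0.0819) or 4 (0.167) and CAL replicates 1 (0.150), 3 (0.0561) or 5 (0.0885). Ribosomal protein genes (28 tested, median 0.14) and fatty acid oxidation genes (27 tested, median 0.15) were higher (camera adjusted p = 0.0266 and 0.0424, 0.834 for both with an estimated correlation). No member of those lists passed over all genes, and adjusted over the list alone 0 ribosomal and 1 fatty acid oxidation gene did. The ribosomal list was lost without HS replicate 4 (0.550) and CAL replicate 4 (0.235), and the fatty acid list without NC replicate 2 (0.0516), HS replicates 2 (0.539) or 3 (0.0903) and CAL replicate 1 (0.741).

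Cortex genes past the threshold in both comparisons moved in opposite directions. Of the genes past the threshold in both comparisons, 31 were higher in HS than NC and lower in CAL than HS, where 2.72 would be shared if the calls were independent. Another 15 were lower and then higher (0.739 if independent), and 0 moved the same way. The 46 genes with opposite directions became 7, 1, 23 and 11 without HS replicates 1 to 4, 24, 29, 22 and 27 without CAL replicates 1, 3, 4 and 6, and 17 with the replicate block. Since both fold changes use the same HS libraries, they are tied without any effect: across genes, which are not independent replicates, the Pearson r was -0.768, against a mean of -0.620 (range -0.633 to -0.606) in 20 simulations of unchanged groups. The simulations drew each gene independently and leave out variation that genes share. Their range is therefore too narrow to judge the distance of the real r. With the HS libraries split so that each comparison used a different pair, the median r over 6 splits was -0.396 (range -0.440 to -0.360). A median of 92.9% (range 87.7 to 96.9%) of the genes called between HS and NC had the opposite sign in CAL against HS.

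**Figure D3:**
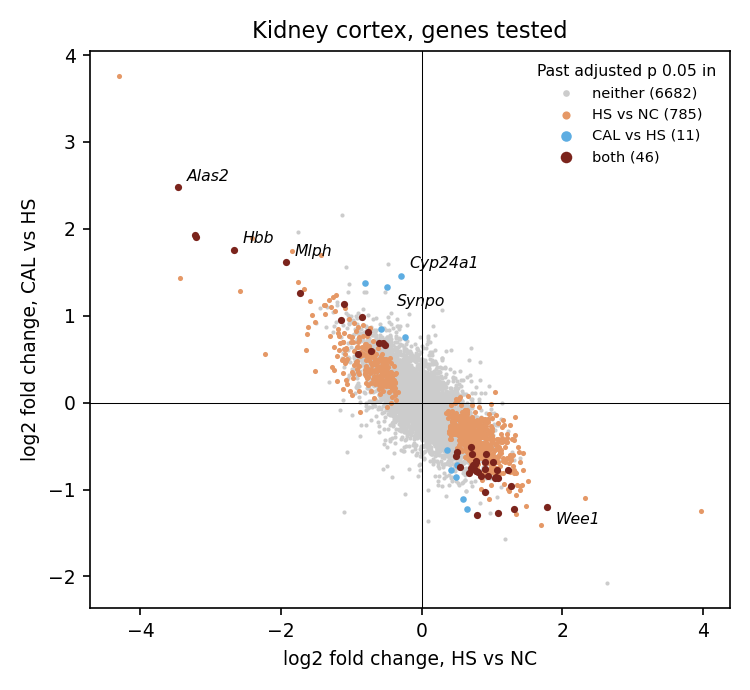
log2 fold change of CAL against HS (vertical) and of HS against NC (horizontal) for the 7524 cortex genes tested, with a point per gene coloured by the comparison it passed. The 46 genes past the threshold in both lie in the upper left and lower right.

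Between CAL and NC cortex, no gene of 7524 passed edgeR quasi-likelihood (smallest adjusted p = 0.0832), with 892 at an unadjusted p under 0.05; DESeq2 gave 28 and voom with library weights 0. The count rose to 4, 2 and 3 without NC replicates 2, 4 and 5, and to 1 and 40 without CAL replicates 1 and 6. The genes with the smallest p, all at an adjusted p of 0.0832, were Hltf (1.16), Glrx (1.31), Ppp1r2 (0.86), Synpo (0.84), Chpt1 (0.71), Hba-a1 (-1.30) and Hba-a2 (-1.31), and Cyp24a1 stood at 1.17 (SE 0.26) with the same adjusted p. Golm1 (-0.87), Gp2 (-2.37) and Plau (-0.54) had an adjusted p of 0.108, and Vdr (0.41, 0.443), Agt (-0.09, 0.888), Scnn1a (-0.06, 0.951) and Slc12a3 (0.23, 0.635) were also not past the threshold.

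As lists, macrophage genes (Aif1 -0.55, Csf1r -0.52, Tyrobp -0.45, C1qb -0.40), antigen presentation genes (RT1-Bb -0.80, RT1-Db1 -0.77, Tapbp -0.63, RT1-A1 -0.56), thick ascending limb genes (Egf -0.67, Umod -0.52, Cldn19 -0.48, Cldn10 -0.29) and erythrocyte genes were lower in CAL than in NC cortex. Their medians were -0.39, -0.50, -0.29 and -0.91, and their limma camera adjusted p 5.87e-04, 0.00284, 0.00630 and 0.00166. With an estimated correlation the adjusted p were 0.292, 0.449, 0.323 and 0.292. The antigen presentation list was lost without NC replicate 1 (0.0762), and the other 3 lists passed with every library left out. No member passed over all genes, and 0 of 8 macrophage, 4 of 14 antigen presentation, 1 of 9 thick ascending limb and 4 of 7 erythrocyte genes were lower adjusted over the list alone.

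In the colon, the sodium, potassium and water transport list was lower under high salt by limma camera (adjusted p = 0.00259), but not with an estimated correlation (0.424) or without HS replicates 3 and 4 (0.108), and no single gene passed. Aqp8, the colonocyte water channel, was at 1407 ± 90.6 CPM in NC, 308 ± 211 CPM in HS and 859 ± 268 CPM in CAL (n = 5, 5 and 6). HS and NC did not overlap (-2.19, SE 0.51, edgeR quasi-likelihood adjusted p = 0.262), and neither did CAL and HS (1.48, SE 0.48, adjusted p = 0.345). Over all tested colon genes, HS and NC did not overlap for 1.40%, where chance gives 0.794%. For CAL and HS it was 0.527%, where chance gives 0.433%. Without HS replicate 3, whose Aqp8 level was far below the others, Aqp8 stood at -1.87 between HS and NC with an adjusted p of 0.00386. Among its neighbours in the lists, Slc9a2 was at -0.71, Slc9a3 at -1.58, Ca4 at -0.59, Guca2a at -0.52, Cldn23 at -1.06, Cldn3 at -0.66, Cldn4 at -0.64 and Clca1 at -0.57, with adjusted p from 0.262 (Cldn23) to 0.627 (Guca2a) by edgeR quasi-likelihood.

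The surface colonocyte list (11 genes, median -0.42) had a limma camera adjusted p of 7.07e-04. The sodium, potassium and water transport list (20 genes, median -0.32) and the tight junction and mucus list (23 genes, median -0.28) had 0.00259 each, and the fatty acid oxidation list (21 genes, median -0.23, mean -0.05) 0.00585. Cell cycle genes were higher (18 genes, median 0.97, adjusted p = 3.25e-08): Mcm3 was at 1.70, Prc1 at 1.64, Mcm2 at 1.45 and Rrm1 at 0.89. These 5 lists passed with every library left out. With an estimated correlation the adjusted p was 0.129 for surface colonocytes and 0.424 for the other 4 lists. Over all genes no member passed by edgeR, and adjusted over the list alone 1 surface colonocyte gene was lower, 1 transport gene higher and 2 lower, 1 tight junction gene lower, 0 fatty acid oxidation genes changed and 5 cell cycle genes were higher. Without HS replicates 3 and 4, left out after the data were seen, the transport and plasma cell lists were lost (0.108 and 0.290). B cell markers (6 genes tested, median 2.12) did not pass as a list (camera adjusted p = 0.584). Over all 13 listed B cell markers, tested or not, the mean log2 CPM was 5.88, 6.64 and 5.30 in HS replicates 3, 4 and 5. It was 2.14 and 2.11 in HS replicates 1 and 2, and from 2.35 to 5.39 in NC. Whether the cell cycle list moves apart from B cell content was not tested. Plasma cell genes (Pou2af1 2.55, Mzb1 1.19, median 0.39) and crypt genes (Cd44 0.68, Mki67 0.80, median 0.40) both had a camera adjusted p of 0.0199 (0.210 and 0.224 with an estimated correlation), with 1 plasma cell gene and 0 crypt genes higher adjusted over the list alone. The plasma cell list was lost without NC replicates 2 (0.0715) or 3 (0.0577) and HS replicate 3 (0.142). The crypt list was lost without NC replicates 3 (0.0577) or 4 (0.109), HS replicates 1 (0.0950), 2 (0.0813), 4 (0.108) or 5 (0.0518), and CAL replicates 2 (0.0703), 3 (0.0749) or 6 (0.0785).

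Of 7217 colon genes, 0 passed between HS and NC by edgeR quasi-likelihood, with 614 at an unadjusted p under 0.05 where chance gives 360.9; DESeq2 gave 15 and voom with library weights 0. Leaving out NC replicate 5, HS replicate 3 or CAL replicate 3 gave 1 gene each. The smallest adjusted p was that of Steap3, a metalloreductase of iron uptake, at 57.5 ± 10.6 CPM in NC, 11.1 ± 7.44 CPM in HS and 38.1 ± 15.2 CPM in CAL (-2.22, SE 0.38, adjusted p = 0.0661, and 0.0335 without CAL replicate 3). Rbp7 (-2.32) and Arntl (-1.47) followed (adjusted p = 0.198 for both), then Cdkn1a (-1.21, 0.211) and Abhd17a (-1.001, 0.252). On the higher side were Flot2 (1.10, 0.262), B4galt4 (1.28, 0.264), Rbm3 (1.10, 0.270), Naaladl1 (4.78, 0.270) and Akr1c14 (1.48, 0.290). The biological coefficient of variation was 0.340 in the colon and 0.166 in the cortex. The colon value includes HS replicate 3, whose small intestine transcripts are described below. Vdr was at 358 ± 156, 257 ± 109 and 366 ± 71.3 CPM in NC, HS and CAL (-0.48, adjusted p = 0.696 for HS against NC), and Scnn1a at -0.29 (0.914). Cyp24a1, Agt and Slc12a3 were too low there to be tested, with group means of at most 0.886, 4.99 and 5.35 CPM.

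HS replicate 3 of the colon carried small intestine transcripts. The ileal bile acid-binding gene Fabp6 stood at 13820 CPM and Reg3g at 40121 CPM in that library, against at most 15.2 and 58.8 CPM in the 15 other colon libraries. Fabp2 was at 2486 CPM, Anpep at 1265 CPM and Apob at 897 CPM, against at most 89.7, 24.8 and 7.996 CPM. The colon genes Aqp8 and Car1 were at 4.81 and 7.21 CPM, against at least 229 and 269 CPM in the others. These genes were singled out after their values were seen. With HS replicate 3 left out, the log2 fold change of HS against NC went from 4.78 to 0.10 for Naaladl1 and from 3.48 to -1.19 for Fabp2 (edgeR quasi-likelihood adjusted p = 0.987 and 0.745).

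**Figure D4:**
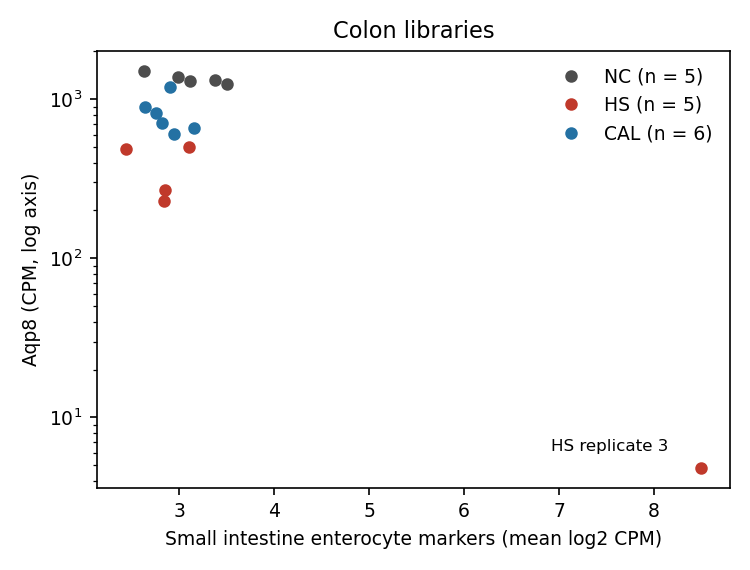
Aqp8 (CPM, log axis) against the mean log2 CPM of small intestine enterocyte markers for the 16 colon libraries, a point per library coloured by group. HS replicate 3 lies at 8.49 and 4.81 CPM, with the other HS libraries between 2.44 and 3.11.

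With calcitriol, the clock output gene Dbp was lower in the colon. Dbp was at 117 ± 26.8 CPM in HS and 21.7 ± 10.7 CPM in CAL (n = 5 and 6; -2.47, SE 0.40, edgeR quasi-likelihood adjusted p = 0.0330), with no overlap between the groups, and at 40.6 ± 36.3 CPM in NC. The call was lost without NC replicate 4 (0.0501), without HS replicates 2 (0.0963), 4 (0.123) or 5 (0.111), and without CAL replicates 1 (0.0996), 2 (0.0704), 4 (0.165), 5 (0.0837) or 6 (0.151). It was also lost with voom and library weights (0.0586), the replicate block (0.152), thinning (0.122), without HS replicates 3 and 4 (0.222), and without HS replicate 3 with marker covariates (0.0957). Dbp was the 1 gene of 7217 that passed between CAL and HS, with 758 at an unadjusted p under 0.05; DESeq2 gave 11 and voom with library weights 0. Over all tested genes the groups did not overlap for 0.527%, where chance gives 0.433%. The count of genes past the threshold was 14 without HS replicate 1, 2 without CAL replicate 3, and 0 without any library that ended the Dbp call. Arntl was at 1.604 (adjusted p = 0.0784), Steap3 at 1.69, Cck at 1.56, Hbb at 2.37 and Arrdc4 at 1.07 (adjusted p = 0.165 for these 4). Vdr (0.51, 0.565) and Scnn1a (0.33, 0.822) did not pass.

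Cell cycle genes were lower in CAL than in HS colon (Mcm3 -2.08, Cdc20 -1.50, Mcm2 -1.10, Rrm1 -1.01; median -0.87; limma camera adjusted p = 7.81e-09). The list passed with every library left out and did not pass with an estimated correlation. No member passed over all genes and 3 were lower adjusted over the list alone. B cell markers (median -2.02, camera adjusted p = 0.718) fell in the same direction without passing. Over all 13 listed B cell markers, tested or not, the mean log2 CPM ran from 2.199 to 5.07 in CAL. Tight junction genes were higher (Cldn23 0.85, Cldn4 0.70; median 0.27; camera adjusted p = 0.0220) and heat shock genes lower (Hsph1 -0.91, Pdia6 -0.81; median -0.33; 0.0246), and neither passed with an estimated correlation, with 0 members adjusted over the list alone. The tight junction list was lost without HS replicate 2 (0.0888) and CAL replicates 1 (0.253) or 5 (0.0866), and the heat shock list without HS replicates 2 (0.241), 3 (0.0966) or 5 (0.0620) and CAL replicates 1 (0.218) or 5 (0.0843), and without HS replicates 3 and 4 together (0.0823). Crypt genes (median -0.31, camera adjusted p = 0.0344) and surface colonocyte genes (median 0.15, 0.0379) stood at 0.394 with an estimated correlation. The crypt list was lost without NC replicate 3 (0.0659), HS replicates 1 (0.153), 2 (0.265), 4 (0.0671) or 5 (0.0697), and CAL replicates 1 (0.343), 4 (0.111), 5 (0.0703) or 6 (0.0713). The surface list was lost without NC replicate 3 (0.0659), HS replicates 2 (0.288) or 4 (0.0577), and CAL replicates 1 (0.145), 5 (0.127) or 6 (0.2003), and with the replicate block (0.0671). Across colon genes the fold changes of HS against NC and of CAL against HS had a Pearson r of -0.747, against a mean of -0.534 (range -0.562 to -0.515) in 20 simulations. These also drew each gene independently, so their range is too narrow to judge the distance of the real r. With the HS libraries split, the median over 20 splits was -0.121 (range -0.216 to 0.220).

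Between CAL and NC colon, 0 of 7217 genes passed by edgeR quasi-likelihood (smallest adjusted p = 0.691, that of Fbxw8 at -1.94), with 278 at an unadjusted p under 0.05; DESeq2 gave 0 and voom with library weights 1. The resistin-like genes Retnlb and Retnla stood at 849 ± 761 and 948 ± 758 CPM in NC and 101 ± 48.2 and 114 ± 71.9 CPM in CAL (-3.08 and -3.03, adjusted p = 0.864 and 0.9999). The other genes with the smallest p were Knstrn (1.99), Pomp (1.94), Klhl12 (1.20), Frmd8 (0.85), Edem2 (0.67), Entpd5 (-0.89) and Egr1 (-1.68), none past the threshold. Smooth muscle genes (Acta2 -1.31, Actg2 -1.29, Cnn1 -1.24, Lmod1 -1.02, Synpo2 -1.19) were lower as vascular and intestinal lists (medians -1.003 and -0.96, limma camera adjusted p = 0.00353 and 0.00851). Both were lost without NC replicates 2 (0.112 and 0.125), 3 (0.0753 and 0.111) or 5 (0.1103 and 0.190), and had adjusted p of 0.673 and 0.689 with an estimated correlation. Ribosomal protein genes (median 0.23, adjusted p = 9.42e-06, lost without NC replicate 4 at 0.0728) were higher. So were interferon response genes (Irf7 0.86, Irf9 0.85, Irf1 0.84, Rtp4 0.61; median 0.52; 0.00130, lost without CAL replicate 1 at 0.108), with adjusted p of 0.782 for both with an estimated correlation. Fatty acid oxidation genes (median -0.22, 0.0244, 0.782 with an estimated correlation) were lost without NC replicates 3 (0.307) or 4 (0.0587), HS replicates 1 (0.0522), 2 (0.0510), 4 (0.0508) or 5 (0.0530), and CAL replicates 2 (0.159) or 3 (0.0913). Plasma cell genes (median 0.36, 0.0309, 0.598 with an estimated correlation) were lost without NC replicates 2 (0.125) or 3 (0.0753) and CAL replicates 2 (0.0754), 3 (0.0767) or 4 (0.0752). Adjusted over the list alone, 0 members of these lists passed.

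The high-salt effect differed between the tissues for 15 of 5992 genes by the edgeR quasi-likelihood test of the difference, with 9 higher in colon relative to cortex and 6 lower, and 932 at an unadjusted p under 0.05. DESeq2 gave 52, voom with libraries of the same group and replicate number as a block across tissues 24, and the filter on 1 CPM in at least 4 libraries 0. Yipf4 was at 0.91 in cortex and -0.64 in colon (difference -1.51, SE 0.27, adjusted p = 0.0121), and this was lost without cortex HS replicates 2 (0.0516) or 4 (0.0812). The cortex and colon effects were 1.26 and -0.82 for Rb1cc1, 0.996 and -0.44 for Chpt1, -1.93 and 0.36 for Mlph, and -0.92 and 0.75 for Nuak2, all with an adjusted p of 0.0378 for the difference. They were -2.58 and 1.53 for Cdc25b (0.0415), -0.53 and 2.27 for Cndp2 (0.0415), -0.84 and 1.34 for Vps9d1 (0.0489), 1.32 and -0.73 for Acer3 (0.0378) and 0.90 and -0.84 for Arhgap5 (0.0423) (edgeR quasi-likelihood adjusted p of the difference in brackets). Each of the 10 genes named for this difference was lost without cortex HS replicate 2 (adjusted p up to 0.150) and without cortex HS replicate 4 (up to 0.128). With the 1 CPM filter all 10 were lost (adjusted p 0.0693 to 0.0941), and with that block Cdc25b (0.118), Cndp2 (0.0912) and Mlph (0.0515). Yipf4 aside, between 7 (Rb1cc1) and 20 (Vps9d1) of the 31 libraries ended the call when left out. The count moved to 2, 9 and 2 without cortex NC replicates 3, 4 and 5, to 5, 0, 6 and 1 without cortex HS replicates 1 to 4, and to 5 and 2 without colon NC replicates 2 and 5. It was 138, 25, 3, 2 and 42 without colon HS replicates 1 to 5 and 23 without colon CAL replicate 1. For CAL against HS, 0 genes differed between the tissues by edgeR quasi-likelihood (smallest adjusted p = 0.0830, with 644 at an unadjusted p under 0.05 and 9 by DESeq2). The count was 42, 4, 1 and 1 without colon HS replicates 1, 2 and 4 and colon CAL replicate 2. The rule names Rangap1 (-1.83), Mgst1 (-2.93), Yipf4 (1.15) and Nucb2 (1.66) there, all with an adjusted p of 0.0830, none past the threshold by edgeR quasi-likelihood. It also names Commd8 (1.13, 0.0830), Cxcl12 (1.33, 0.107), Scamp1 (1.02, 0.124), Aldh2 (-1.04, 0.0830), Rbpms (-2.22, 0.0830) and Rtel1 (-1.64, 0.0830) there, none past the threshold by edgeR quasi-likelihood.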

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

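The test of Alas2 and the values of blood transcripts without Fcgr3a and Itga2b and in CAL against HS were chosen after the results they weigh were seen. So were the count of clock genes and the 3 tests on colon HS replicate 3. The other tests here were written down before their own results, though thinning was chosen after the data were seen. The erythrocyte and clock patterns came from these same data. The search covered 104 sets of values, each a measure over the 4 to 6 libraries of a group. Of these, 11 held a library apart from its group by Dixon's test of the gap to its neighbour. Chance gives about 1 in 20, or 5.2.

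In the cortex, HS replicate 3 lay at 19.5 on the second principal component and the other HS libraries between -7.66 and -3.83. Vdr in cortex HS replicate 4 stood at 131 CPM, against 87.0 to 88.7 CPM in the other HS libraries. Total counts stood apart in cortex CAL replicate 1 (2265164, others 530018 to 764666), cortex NC replicate 2 (1239310, others 513294 to 723752) and colon HS replicate 1 (918820, others 305700 to 475450). In the colon, Vdr in NC replicate 4 stood at 636 CPM, against 274 to 308 CPM in the other NC libraries. Agt in colon CAL replicate 5 (3.87 CPM, others 0) rests on 2 counts, and Cyp24a1 in colon CAL replicate 2 (3.11 CPM, others 0) on 1 count. Slc12a3 in colon CAL replicate 3 stood at 19.3 CPM, against 0 to 5.80 CPM in the other CAL libraries, with 12 counts over the group. Colon HS replicate 3 stood apart in the mean log2 CPM of small intestine markers (8.49, others 2.44 to 3.11) and in the share of counts in its 10 most counted genes (15.3%, exact 95% interval 15.2 to 15.4%, others 8.20 to 10.02%).

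The difference between tissues in the high-salt effect passed the edgeR quasi-likelihood test for Cdc25b (colon minus cortex 4.08), Cndp2 (2.80), Mlph (2.29), Vps9d1 (2.24), Nuak2 (1.67), Chpt1 (-1.42), Yipf4 (-1.51), Arhgap5 (-1.69), Acer3 (-2.02) and Rb1cc1 (-2.05). Of 100 splits of the libraries, the real one included, 3 gave at least the 15 genes, a share under the 0.05 set beforehand. These splits break up the effect within each tissue, so they do not stand for an equal effect in both tissues. They therefore do not exclude chance for a difference between the tissues. The highest of the other splits gave 42 genes, more than the real split. Whether a structure of the samples beyond the groups lies behind this was not tested. Without colon HS replicate 1, whose total was far above its group, 138 genes differed, and without cortex HS replicate 2, 0.

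Erythrocyte transcripts were lower in HS than in NC cortex (Hba-a1 -3.22, Hbb -2.67) and higher again in CAL. Reads shared between the similar haemoglobin genes cannot explain it alone, since Alas2, which is no haemoglobin gene, was at -3.46 (SE 0.57), and thinning every library to the shallowest left Hbb at -2.77 (SE 0.34), which argues against depth. Less residual blood in HS samples may explain part of the fall. Together, 20 neutrophil and platelet transcripts (20 to 155 counts per library) were at -0.66 (SE 0.08, exact permutation p = 0.00794) in HS against NC. At 0.13 (SE 0.12, exact permutation p = 0.419) in CAL against HS they give the rise in CAL little support. The bound written beforehand, that less blood would bring them to -1 or below, was missed by more than 2 SE. As far as they come from blood, they argue against less blood as the source of the whole fall. Fcgr3a and Itga2b held 65.1% of those counts in the cortex, and whether these come from blood or from tissue cells was not tested. The other 18 genes (7 to 58 counts per library), set apart after that result, were at -0.88 (SE 0.22, exact permutation p = 0.00794) in HS against NC. That value reaches -1 within its error, and in CAL against HS they were at 0.46 (SE 0.27, exact permutation p = 0.152). The haemoglobin share moved further, by -2.73 and 1.86 in these comparisons. A change in circulating red cells or their precursors under salt and calcitriol was not tested. Its share of the fall cannot be told apart from that of blood left in the tissue.

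Some clock transcripts differed between HS and NC in the cortex, while in the colon none passed (edgeR quasi-likelihood, Arntl nearest with adjusted p = 0.198). No single library decides the shift of Nr1d2 in the cortex, whose fold change of 0.94 stayed at or above 0.84 with each library left out. Of 11 clock genes tested in both tissues, 9 moved the same way (Arntl -1.43 in cortex and -1.47 in colon, Per2 1.13 and 0.67, Tef 0.31 and 1.70), with Clock and Nr1d1 the exceptions. A different hour of tissue collection in the HS group may explain such a shift, and cannot be told apart from an effect of diet, since any such hour would coincide with the group and no hour was used here.

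Colon HS replicate 3 held small intestine transcripts, and all 3 measures set for it (small intestine markers, Aqp8 and Car1) lay outside the range of the 15 other colon libraries. The small intestine list stood at 8.49 in that library, against at most 3.50 in the 15 others. Another gut segment in the sample stays a candidate explanation. The genes of the small intestine list were fixed beforehand. That list, Aqp8 and Car1 were singled out only after their values were seen, so the 3 measures do not test this explanation. Low depth is argued against by the library's total of 415913, which lies inside the range of the others. A swap with another colon library of the series cannot account for these transcripts, since a colon library would hold them under any labels. Such a swap would only change the group of that library. The gap of 4.99 in small intestine markers to the next highest library would be the same with or without it, and does not test it. No biological explanation was tested.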

How the results depend on the processing

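The alternatives that thin the libraries, leave out erythrocyte genes, add the haemoglobin share or leave out more than 1 library were chosen after seeing the data. The cause of each change was not tested unless given.

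For the genes past the threshold between HS and NC in the cortex (831), DESeq2, its size factors, no filter, a 1 CPM filter, a fit to the compared groups, robust empirical Bayes, voom weights and the replicate block gave counts within 1.5 times (613 to 1032). Thinning to the shallowest library gave 422, with 366 shared and fewer genes tested. The haemoglobin share as a covariate gave 2, with 0 shared, and 77.9% of the variance of that share lay between the groups. Leaving out single libraries gave 324 to 961.

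For CAL against HS in the cortex (57), DESeq2 gave 105, no filter 128, the compared groups alone 30, the replicate block 22, thinning 19, leaving out erythrocyte genes 33 and the haemoglobin covariate 1; single libraries left out gave 2 to 80. For CAL against NC (0), DESeq2 gave 28, no filter 83, the 1 CPM filter 7, robust empirical Bayes 2, the replicate block 42 and thinning 1; single libraries left out gave 0 to 40.

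In the colon, HS against NC (0) gave 15 with DESeq2, 59 with no filter, 1 with robust empirical Bayes, 1 without HS replicates 3 and 4, and 4 without HS replicate 3 and with marker covariates; single libraries left out gave 0 to 1. CAL against HS (1) gave 11 with DESeq2, 66 with no filter, 5 with the 1 CPM filter, 2 with robust empirical Bayes. It was 0 with voom weights, the replicate block, thinning, without HS replicates 3 and 4, and without HS replicate 3 with marker covariates; single libraries left out gave 0 to 14. CAL against NC (0) gave 1 with no filter, 2 with the compared groups alone, 1 with voom weights and 2 without HS replicate 3 with marker covariates; single libraries left out gave 0 to 0.

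The difference between tissues in HS against NC (15) gave 52 with DESeq2, 0 with the 1 CPM filter, 24 with voom and the replicate number within a group as a block across tissues (the labels do not say that a number marks an animal), and 0 to 138 with single libraries left out. For CAL against HS (0) these were 9 with DESeq2, 1 with that block, and 0 to 42.

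With an estimated correlation, 0 lists passed in any comparison of either tissue. The replicate block gave 7 marker lists for CAL against NC in the cortex (3 without it), and in the colon 5 marker lists for HS against NC (3), 6 gene lists for CAL against NC (3) and 6 marker lists (3). Without HS replicates 3 and 4, the colon had 8 gene lists for HS against NC (4), 6 marker lists for CAL against HS (2) and 5 for CAL against NC (3). Single libraries left out gave, for gene and marker lists in the cortex, 0 to 2 and 1 to 2 (HS against NC), 1 to 2 and 1 to 4 (CAL against HS), and 0 to 2 and 3 to 6 (CAL against NC). In the colon these were 4 to 10 and 1 to 5, 1 to 6 and 0 to 4, and 2 to 6 and 0 to 5.

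With the HS libraries split, the r between the fold changes of HS against NC and of CAL against HS moved to -0.396 in the cortex and -0.121 in the colon. The shared libraries no longer tie them there. Each comparison then also used fewer HS libraries, which adds noise and weakens r, so the move is not due to the tie alone. The covariance of the fold changes went from -0.129 to a median of -0.0897 in the cortex and from -0.181 to -0.0435 in the colon. With single libraries left out, r ran from -0.802 to -0.717 in the cortex and from -0.821 to -0.672 in the colon.

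Among named genes past the threshold, the haemoglobin covariate reversed 11 fold changes: Aida -0.13, RT1-Ba 0.39, Arntl 0.0333, Usp2 -0.26, Tmem52b -0.22, Rac2 0.26, Cdc25b 1.31, Hba-a3 0.68, Alas2 0.26 and Hbb 0.34 for HS against NC, and Hbb -0.16 for CAL against HS. The share includes Hba-a3 and Hbb themselves, and most of its variance lay between the groups, so these reversals do not test the genes. No other alternative reversed a fold change past the threshold. Fold changes not past it did change sign, such as Fabp2 in the colon (3.48, and -1.19 without HS replicate 3). Over single libraries left out, 4348 of 4741 values of named genes stayed on their side of the threshold, 337 fell below it and 56 passed it. Replicate numbers showed no clear pairing within the tissues: after removal of group means, 0 of 13 cortex pairs and 4 of 15 colon pairs with the same number correlated above 0.1. Across tissues 6 of 15 pairs did (highest 0.246), with a consensus correlation of 0.0719, so a weak pairing of cortex with colon is not excluded.

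The share of counts in the 10 most counted genes of colon HS replicate 3 is 15.3% of all counts and 9.39% of counts in tested genes. On simulated counts with the same groups and totals, a gene changed by 0.5 on the log2 scale between HS and NC was recovered in 19.0% of cortex and 1.54% of colon cases. Depth was not separated there from the variation between samples (biological coefficient of variation 0.166 and 0.340). The colon values include HS replicate 3.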

Other observations

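The counts of other splits and the bounds on a shared response were written down before the results were seen. Trpv5 (2.33) and Calb1 (1.32) rose in the high-salt cortex, while Slc12a3, a marker of the distal convoluted tubule, stood at -0.02. The list of distal convoluted and connecting tubule genes (8 genes, 2 higher over all genes and 2 adjusted over the list alone) had a limma camera adjusted p of 0.0858. In CAL cortex Trpv5 stood at 9.16 ± 4.84 CPM and Calb1 at 1039 ± 588 CPM (n = 6), between the NC and HS means, and Trpv5 was at -1.10 against HS (edgeR quasi-likelihood adjusted p = 0.153).

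Chance alone is an unlikely source of the numbers of cortex genes past the threshold. Between HS and NC (831), 1 of 100 splits of the libraries, the real one, gave as many, and the highest other gave 315. Between CAL and HS (57) it was again 1 of 100, with 8 in the highest other. Splits do not test differences that go with the groups, such as blood content or hour of collection. By these splits, chance cannot be excluded for the numbers of cortex lists past the threshold that lie above 0. The splits count lists and do not weigh any single list, such as the erythrocyte list. The haemoglobin share, tested apart by exact permutation, had an adjusted p of 0.0159 in HS against NC cortex. For HS against NC 78 of 100 splits gave at least the 1 marker list (highest other 7). For CAL against HS it was 77 the 2 gene lists (7) and 45 the 3 marker lists (7). For CAL against NC it was 91 the 1 gene list (11) and 55 the 3 marker lists (9). A count of 0 is not tested by splits, since all 100 give at least 0. This applies to the gene lists of HS against NC (highest other 11) and the genes of CAL against NC (highest other 14).

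In the colon, chance cannot be excluded for any count above 0. For genes, 6 of 100 splits gave at least the 1 of CAL against HS (highest other 76), while the 0 of HS against NC (highest other 136) and the 0 of CAL against NC (highest other 1) are reached by all 100 and test nothing. For gene and marker lists, 73 and 68 splits gave at least the 4 and 3 of HS against NC (highest other 14 and 9), 87 and 57 the 3 and 2 of CAL against HS (10 and 7), and 71 and 43 the 3 and 3 of CAL against NC (10 and 7). The splits that call 76 and 136 genes exceed the real counts. Whether a structure of the colon samples other than the groups lies behind them was not tested. For the difference between tissues in CAL against HS the real count is 0, which all 100 splits reach, so nothing is tested about chance (highest other 35).

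A response shared by cortex and colon was tested by the Pearson r across genes of the fold changes in the 2 tissues. For HS against NC the r was 0.0314, and 50 of 100 relabellings gave one as high (highest other 0.388). For CAL against HS it was 0.0709, with 33 of 100 as high (highest other 0.247). The bound written beforehand was that 5 or more relabellings as high would exclude a shared response. It was met but was wrong, since relabellings that reach 0.388 and 0.247 leave room for a weak shared response, which may be present or absent at these values of 0.0314 and 0.0709.

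Gene families by symbol stem were compared for a surplus of cortex genes past the threshold, higher or lower, in HS against NC and in CAL against HS. Of 87 families none passed an exact hypergeometric test with Benjamini-Hochberg adjustment over families, directions and both comparisons. The nearest was the RT1 histocompatibility family, with 4 of 13 tested genes lower in HS than in NC (adjusted p = 0.357).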
